A study of Ovis aries with 12 samples.

How the data were processed

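The series holds stranded mRNA libraries of right ventricular free wall of lambs, 4 in the fetal, 4 in the control and 4 in the shunt group. Per the labels' protocols, RNA was isolated with the RNeasy Plus Universal Mini kit, libraries were made with the QIAseq Stranded mRNA kit, and read pairs of 75 bases were sequenced on a NextSeq instrument, and the tissue had been snap frozen. The authors deposited 1 table of raw counts per gene, called total counts per the file headers, with 27054 rows and 12 columns, each matched to a sample through its library name. Of these rows 8671 had no count in any library. The aligner, the counting program, the genome build and whether counting used strand are not given in the sources used here. Genes that overlap on opposite strands, and genes with near-identical copies, may therefore share or lose reads, and no coordinates are given.

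Names came from the deposited table, in which 24377 rows repeat the Ensembl identifier and 2677 hold a name, 1850 of them numbered copies of a shared name. The reference table used here for sheep has 35057 rows, 0 of them with an Ensembl identifier, and 0 identifiers matched it. Genes without a symbol were tested and counted but not named, and 1 gene with a symbol is not reported here.

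Counts were analysed in R 4.3.3. Genes were kept with filterByExpr of edgeR 4.0.16 by group, which left 13065, and scaled by TMM (trimmed mean of M values), with factors from 0.455 to 1.61. One quasi-likelihood model with the 3 groups (glmQLFit, robust) was fitted to the 12 libraries, so that they share the estimate of spread, and control against fetal, shunt against control and shunt against fetal were tested with glmQLFTest. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. Adjusted p-values printed for genes are from this edgeR test unless named otherwise, and the standard error is the size of the log2 change divided by the square root of F. CPM values are TMM-scaled, and log2 CPM used a prior count of 2. Total counts ranged from 19111348 to 44946875. Shares of counts have Wilson intervals at 95%, ratios of summed counts have exact binomial intervals, and shares were compared with two-sided exact permutation tests.

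Before the data were examined, 32 gene lists with 683 different members were fixed for the tissue and the load. Of the members 104 matched a name in the table. Of the lists 26 had a tested member, and 15 had the 3 members needed for a set test with camera of limma 3.58.1 (preset correlation 0.01, Benjamini-Hochberg over the lists, repeated with an estimated correlation). The lists for calcium handling, ion channels and gap junctions, red blood cells, epicardium, nerve and sex-linked genes had 0 tested members and were not used here. With few members tested per list, a list result speaks for those members alone. Adjusting over the list alone leaves the p-value of a single tested member unadjusted, and it makes no allowance for the number of lists. The genes to be named were fixed by rule. For control against fetal and shunt against control these were the 8 genes per direction with the largest log2 change among called genes with a symbol, a mean of at least 5 CPM in the higher group and no overlap between libraries, and up to 4 members of each list with the smallest p. A fixed panel was added in each comparison, of which NPPA, NPPB, VEGFA, KDR and CPT1B were tested. For shunt against fetal, the rule took the panel and 3 genes per direction, and the list members given there, like the genes called in 2 comparisons, were chosen after their values were seen.

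Replicates were compared before averaging. The smallest chi-square per gene between libraries of a group was 25.2, so no library was a mere repeat of the counts of another. This does not show that libraries of a group came from separate animals.

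The tests were tried on simulated counts drawn from the fitted means and library sizes with a known set of genes changed. For control against fetal, 3%, 28.4% and 77.3% of genes changed 1.5-, 2- and 4-fold were recovered, and 3 unchanged genes among 12928 tested were called. For shunt against control these were 3%, 32.8% and 81.8%, with 5 unchanged genes called among 12942. For shunt against fetal they were 0%, 14.9% and 72.7%, with 2 among 12955. Changes of 2-fold and less were thus mostly missed. Apart from the changed genes, these counts had the same mean and dispersion per gene in every group. The wider spread of the shunt libraries was therefore absent, and the rates for the shunt comparisons may not hold for the data. In a simulated shunt group midway between control and fetal on the log scale, run on 13065 genes, 97.3% of called genes lay on the fetal side. The simulated unchanged shunt groups were 20 sets of counts drawn with the dispersion of each gene, each gene independently of the others.

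Alternatives fixed beforehand were DESeq2-style size factors, library totals, TMM after removing mitochondrially encoded genes, the Wald test of DESeq2 1.42.0, limma-voom with quality weights, no filter beyond 1 count, at least 1 CPM in at least 4 libraries, a test against a fold of 1.5 (glmTreat), a fit of the 8 libraries compared, the replicate number as a block, and leaving out each library. Leaving out shunt 1 and shunt 2 together, the mitochondrial share as a covariate and thinning the other counts of each library to 7140136 were chosen after seeing the data. Thinning was drawn once for the counts and 20 times for the test of lost depth in shunt against control. No sample was left out of the main analysis.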

Results

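Right ventricular free wall of sheep was profiled by mRNA sequencing in 12 libraries. There were 4 from fetal lambs, 4 from control lambs aged 4 to 6 weeks and 4 from shunt lambs of the same age range. The shunt lambs carried a graft between the aorta and the pulmonary artery, placed by surgery before birth, which sends blood from left to right and puts a pressure load on the right ventricle. Control against fetal lambs follows the ventricle over birth and the first weeks of life. Shunt against control lambs compares loaded and unloaded ventricles of the same age, and shunt against fetal lambs sets the loaded ventricle beside the fetal one. Total counts per library were 27330975, 19111348, 19975587 and 24846301 in the fetal group, 44946875, 20041416, 37991646 and 26418438 in the control group, and 26090943, 24944197, 42774036 and 26615226 in the shunt group. The labels do not state that each library came from a different animal, so the p-values measure the spread between these libraries, which may be technical. Of 13065 genes tested, 479 carried a gene symbol in the deposited table, and the genes named here come from those 479.

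Transcripts of the 13 protein genes of the mitochondrial genome took a large and uneven part of the counts. Their share was 33.1% ± 6.39 in fetal, 46.1% ± 2.88 in control and 61.1% ± 13.2 in shunt libraries (SD, n = 4 each). Two-sided exact permutation tests gave p = 0.0286 for control against fetal and for shunt against fetal, the smallest that 4 against 4 libraries can give, and p = 0.0857 for shunt against control. Adjusted over the 3 comparisons by Benjamini-Hochberg, these exact p-values were 0.0429, 0.0429 and 0.0857. Shunt 1 and shunt 2 stood apart at 72.6% (95% Wilson interval 72.57 to 72.60) and 71.4% (71.36 to 71.39). Shunt 3 was at 54.6% (54.61 to 54.64) and shunt 4 at 45.6% (45.62 to 45.66), and these intervals cover counting error only. Shunt 1 and shunt 2 kept 7152139 and 7140136 counts on all other genes, against 10702663 to 24976602 in the fetal and control libraries. On the first principal component of log2 CPM, with 34.15% of the variance, shunt 1 and shunt 2 lay at 77.1 and 106 and the other libraries between -46.9 and 15.5. The second component, with 18.0%, separated fetal from control libraries. Pearson correlations across genes between libraries of one group were 0.960 to 0.968 in the fetal, 0.958 to 0.970 in the control and 0.896 to 0.943 in the shunt group. Log2 changes are relative to TMM scaling. With library totals as the only scaling, the median of all genes shifted by -0.41 for control against fetal, -0.61 for shunt against control and -1.02 for shunt against fetal.

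**Figure D1:**
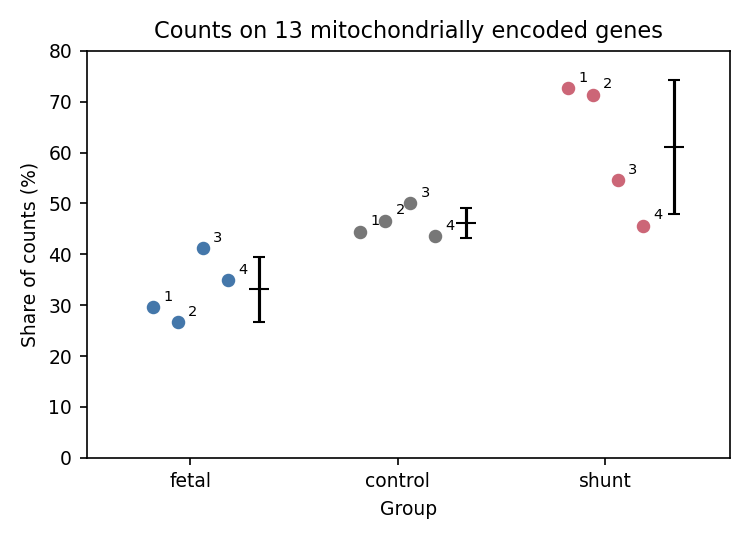
Share of all counts (%) on the 13 mitochondrially encoded genes in each library, by group, with points for libraries, their replicate numbers, and black bars for the group mean ± SD (n = 4). Shunt 1 and shunt 2, at 72.6% and 71.4%, lie above every other library, and shunt 4, at 45.6%, lies within the control range.

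**Figure D2:**
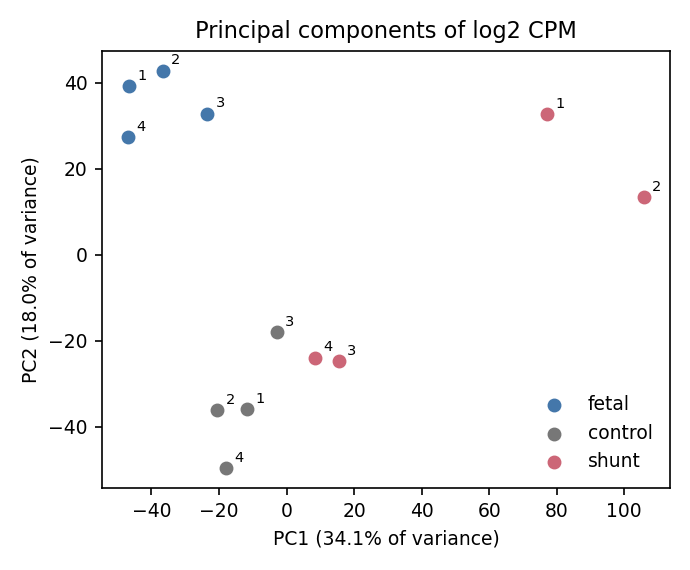
Position of the 12 libraries on the first and second principal components of log2 CPM, coloured by group and numbered by replicate. Shunt 1 and shunt 2 lie at 77.1 and 106 on the first axis, and fetal and control libraries part on the second.

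From the fetal to the control ventricle, the cell division genes CDK1, AURKA and CCND2 fell, and the lipid genes FABP5, LPL, UCP2 and SLC25A20 rose. CDK1 (ENSOARG00000004318), the kinase that drives entry into mitosis, fell from 17.9 ± 6.71 to 3.37 ± 1.21 CPM (SD, n = 4), a log2 change of -2.42 (SE 0.554, edgeR adjusted p = 0.0227). AURKA, a kinase of the mitotic spindle, fell by 1.93 on the log2 scale (SE 0.422, edgeR adjusted p = 0.0177), and CCND2, a D-type cyclin, fell by 1.44 (SE 0.338, adjusted p = 0.0244). CCN2, a secreted matrix protein also known as connective tissue growth factor, fell from 30.8 ± 16.5 to 2.47 ± 1.07 CPM (log2 -3.63, SE 0.707, adjusted p = 0.0122). IGFBP5, which binds insulin-like growth factors, fell from 166 ± 34.7 to 56.1 ± 22.04 CPM (adjusted p = 0.0252). The cytoplasmic actin ACTB, the urokinase gene PLAU and the prostaglandin transporter SLCO2A1 had log2 changes of -1.35, -1.34 and -1.33 (edgeR adjusted p = 0.0293, 0.0137 and 0.0102).

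ALDH1A1 (ENSOARG00000012705), an enzyme that makes retinoic acid, rose from 31.7 ± 20.1 to 433 ± 149 CPM, a log2 change of 3.77 (SE 0.601, edgeR adjusted p = 0.0039). PITX3 (ENSOARG00000017626), a homeobox transcription factor, had 0 to 5 counts in each fetal library and 7 in sum, against 871 in the controls. The ratio of summed counts scaled by library size was 118, with an exact 95% interval for counting error of 56.9 to 294 (edgeR adjusted p = 0.000988). FABP5 (ENSOARG00000008976), which carries fatty acids in the cytoplasm, rose from 44.1 ± 16.5 to 207 ± 62.9 CPM (log2 2.23, SE 0.350, adjusted p = 0.00292). The integrin gene ITGB6 rose from 3.46 ± 1.71 to 22.2 ± 3.62 CPM (log2 2.69, SE 0.347, adjusted p = 0.000973), and IDH1, the cytosolic isocitrate dehydrogenase, rose by a log2 change of 2.40 (SE 0.337, adjusted p = 0.00143). SERPINF1, PDXK and TUBA4A, which encode a secreted serpin, pyridoxal kinase and an alpha-tubulin, had log2 changes of 1.99, 1.80 and 1.77 (adjusted p = 0.0385, 0.00405 and 0.0111). Except for LPL, UCP2 and SLC25A20, the genes in these opening accounts were chosen by a rule that required no overlap. Among LPL, UCP2 and SLC25A20 only UCP2 overlapped between the 4 fetal and 4 control libraries, at 1.41 to 2.14 and 1.88 to 16.06 CPM. FABP5, ACTB, TUBA4A and SLC25A5 have close relatives or copies in mammalian genomes, and how shared reads were counted is not given in the sources used here, so their levels are uncertain.

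All 7 tested genes of fatty acid oxidation and lipid uptake had a positive log2 change, with a median of 0.59, or 0.19 with library totals. UCP2, a mitochondrial carrier, rose by 2.42 (SE 0.495, edgeR adjusted p = 0.0128). Lipoprotein lipase LPL rose by 1.77 (SE 0.365, adjusted p = 0.0132) and the carnitine-acylcarnitine carrier SLC25A20 by 0.89 (SE 0.208, adjusted p = 0.0232). These 3 passed over all genes and 4 adjusted over the list alone, but with library totals none of the 3 was called (edgeR adjusted p = 0.0517 for UCP2, 0.0504 for LPL and 0.197 for SLC25A20). CPT1B stood at 0.50 (SE 0.228, adjusted p = 0.261). As a set they were higher in controls by limma's camera (adjusted p = 0.000516 over 15 lists, and adjusted p = 0.45 with an estimated correlation). All 6 nuclear-encoded genes of oxidative phosphorylation had positive changes, from 0.41 for ATP5PD to 0.79 for NDUFB6 and with a median of 0.50, or 0.11 with library totals, with 0 called over all genes and 4 adjusted over the list alone (camera adjusted p = 0.00112, and adjusted p = 0.45 with an estimated correlation). All 13 mitochondrially encoded genes were positive too, with a median of 0.84, or 0.46 with library totals, and 0 called over all genes or adjusted over the list alone (camera adjusted p = 3.09e-05, and adjusted p = 0.458 with an estimated correlation). These 13 genes together make up the mitochondrial share of each library and are not independent of each other. Across all genes edgeR gave 2408 with an unadjusted p under 0.05.

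Both tested proliferation genes, CDK1 and AURKA, fell, also adjusted over the list alone. Of 6 growth regulators of cardiomyocytes CCND2 fell and 2 passed adjusted over the list alone, the other being PIM1 at -1.31 (SE 0.439, edgeR adjusted p = 0.105). None of 5 cell cycle inhibitors was called over all genes, and CDKN1A, at 1.36 (SE 0.406, adjusted p = 0.0699), passed adjusted over the list alone. The sarcomere genes TPM1, MYOZ2 and MYL2 stood at 0.49, 0.28 and -0.21 with no call. CNN1, the 1 tested gene of the immature contractile list, stood at -1.72 (SE 0.628, adjusted p = 0.149) and passed adjusted over the list alone. Of 6 wall stress genes none was called over all genes, and 2 with positive and 1 with negative change passed adjusted over the list alone. NPPB, the gene of B-type natriuretic peptide, averaged 223 ± 132 CPM in fetal and 3.65 ± 4.40 CPM in control libraries with no overlap (log2 -5.90, SE 1.85, adjusted p = 0.104). NPPA, the atrial natriuretic peptide gene, averaged 156 ± 146 and 17.4 ± 22.2 CPM (log2 -3.15, SE 1.68, adjusted p = 0.355).

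Of 8 fibroblast and matrix genes 7 had a negative change. CCN2 fell and TIMP3, an inhibitor of matrix proteases, rose by 1.57 (SE 0.308, edgeR adjusted p = 0.0106). TIMP1 stood at -0.78 (SE 0.219, edgeR adjusted p = 0.053), and adjusted over the list alone 1 rose and 4 fell (camera adjusted p = 0.0506, and adjusted p = 0.45 with an estimated correlation). The endothelial genes KDR, a receptor of vascular endothelial growth factor, and AQP1 stood at -0.75 (SE 0.220, adjusted p = 0.0641) and -0.26, and KDR passed adjusted over the list alone. The growth factor gene VEGFA stood at -0.35 (SE 0.194, adjusted p = 0.356), and none of the 4 angiogenic genes passed either way. CNN1 and RGS4, both on the pericyte and smooth muscle list, and MRC1, 1 of 3 myeloid markers at 1.09 (SE 0.329, adjusted p = 0.0735), passed adjusted over their lists alone. GNLY, a granule protein of cytotoxic lymphocytes, rose from 9 to 95 summed counts (ratio 9.99, exact 95% interval for counting error 5.05 to 22.5, edgeR adjusted p = 0.0417) as the 1 call among 4 lymphocyte markers. B2M, the light chain of class I molecules, rose by 1.36 (SE 0.244, adjusted p = 0.00688) as the 1 call among 7 antigen presentation genes. PEG10, the 1 tested gene of the imprinted list, stood at -1.40 (SE 0.449, adjusted p = 0.0918) with an unadjusted p under 0.05. THRB, a thyroid hormone receptor and 1 of 4 metabolic regulators, stood at 1.05 (SE 0.324, adjusted p = 0.078) and passed adjusted over the list alone. The adipocyte, atrial, lymphatic, cardiac transcription factor, glycolysis, immediate early, heat shock and hypoxia lists had no member that passed over all genes or over the list alone.

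In all, 675 of 13065 genes differed between control and fetal libraries by edgeR's quasi-likelihood test, 348 higher and 327 lower in controls, of which 24 and 13 carried a symbol. The 4 and 4 libraries did not overlap for 2526 genes (19.3%, against 2.86% by chance). The count was 259, 311 and 364 without fetal 1, fetal 2 and fetal 4, and 378, 372 and 273 without control 1, control 2 and control 4. Of the 22 genes called and named by the rule, 12 stayed called without each single library of the groups compared. The other 10, CDK1, AURKA, CCND2, IGFBP5, ACTB, PLAU, SERPINF1, LPL, SLC25A20 and GNLY, kept their sign and lost the call in at least 1, with edgeR adjusted p up to 0.115. Without shunt 1 and shunt 2, which enter the model's estimate of spread, the count was 1672 and included 673 of the 675 genes and all 22 named. With library totals 16 of the 22 stayed called, and SERPINF1, UCP2, LPL, SLC25A20, TIMP3 and GNLY did not.

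**Figure D3:**
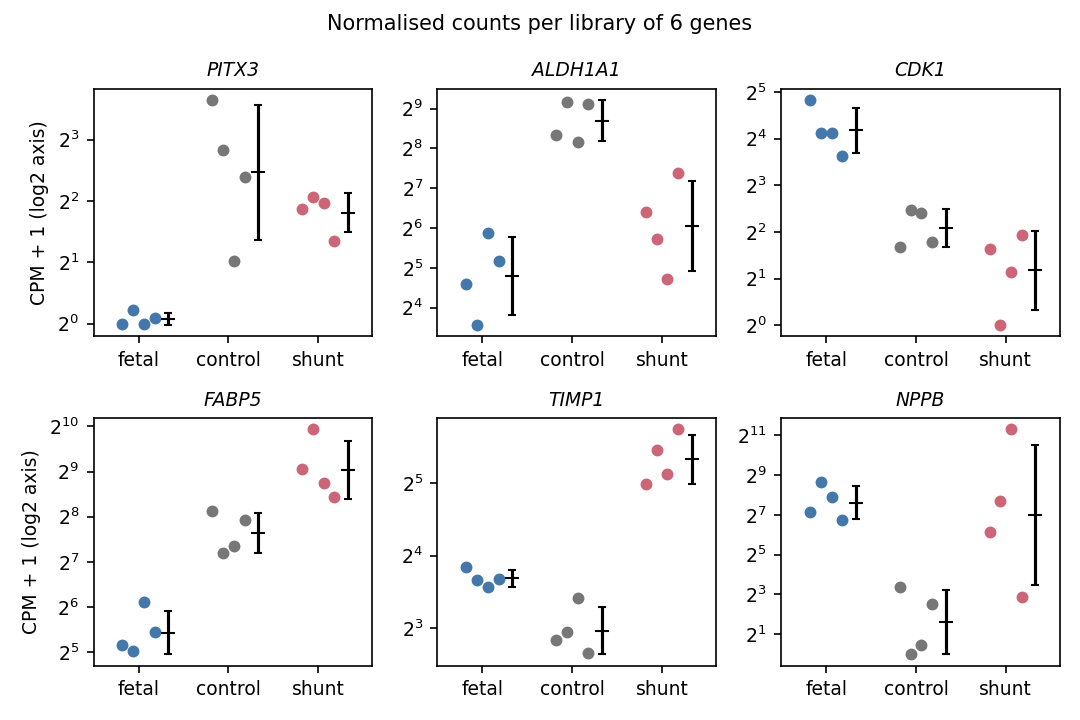
Normalised counts of 6 genes in each library, as CPM + 1 on a log2 axis, with points for libraries and black bars for the mean ± SD of the log2 values (n = 4 per group). PITX3, ALDH1A1 and FABP5 lie higher and CDK1 lower in control than in fetal libraries, TIMP1 is higher in every shunt library than in any other, and the shunt values of NPPB run from 6.18 to 2520 CPM.

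Between shunt and control ventricles of the same age, TIMP1 (ENSOARG00000013157), which inhibits matrix metalloproteinases, had the smallest p of the named genes. It averaged 40.01 ± 9.77 CPM in shunt against 6.94 ± 1.90 CPM in control libraries (SD, n = 4), a log2 change of 2.53 (SE 0.228, edgeR adjusted p = 0.000209). The 4 shunt values were 30.8, 42.8, 33.9 and 52.5 CPM and the highest control value was 9.65 CPM. FABP5 was higher, at 570 ± 281 against 207 ± 62.9 CPM (log2 1.46, SE 0.341, adjusted p = 0.0403). SLC25A5, an ADP/ATP carrier of the inner mitochondrial membrane, was higher by 1.11 (SE 0.198, adjusted p = 0.0276) and PUS1, a pseudouridine synthase, by 1.35 (SE 0.271, adjusted p = 0.0344). The calcium-binding protein CIB1, the cholesterol-esterifying enzyme LCAT and C3H12orf29 were higher by 1.16, 1.13 and 1.08 (edgeR adjusted p = 0.0336, 0.0374 and 0.0343). ATF4, a transcription factor of the integrated stress response, was higher by 0.86 (SE 0.213, adjusted p = 0.0455).

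ALDH1A1 was lower in shunt libraries, at 81.7 ± 61.4 against 433 ± 149 CPM in controls (log2 -2.41, SE 0.566, edgeR adjusted p = 0.0427). YAP1, the transcriptional effector of the Hippo pathway, was at 8.01 ± 1.49 against 15.9 ± 1.93 CPM (log2 -0.98, SE 0.186, adjusted p = 0.0336). The growth factor gene FGF7 had a log2 change of -1.28 (SE 0.238, adjusted p = 0.0336) and gelsolin, GSN, which severs actin filaments, of -1.29 (SE 0.277, adjusted p = 0.0374). Hormone-sensitive lipase, LIPE, was at -1.90 (SE 0.496, adjusted p = 0.0487) and muscle glycogen phosphorylase, PYGM, at -0.96 (SE 0.244, adjusted p = 0.0462). The protease gene FURIN and the growth hormone receptor gene GHR were at -0.93 and -0.83 (edgeR adjusted p = 0.0428 and 0.0457). PEG10 was lower too, with 21 counts summed over the shunt and 177 over the control libraries (ratio 0.191, exact 95% interval for counting error 0.115 to 0.30, edgeR adjusted p = 0.0374). The naming rule required no overlap between the 4 shunt and 4 control libraries for these genes except PEG10, which did not overlap either.

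The natriuretic peptide genes varied widely among shunt libraries and were not called. NPPB was at 68.4, 205, 2520 and 6.18 CPM in shunt 1 to shunt 4 and at 9.38 CPM or less in controls (log2 7.55, SE 1.99, edgeR adjusted p = 0.056). NPPA was at 69.3, 142, 3589 and 9.85 CPM against 0.69 to 49.7 CPM (log2 5.76, SE 1.90, adjusted p = 0.0895), and passed adjusted over the atrial list alone. Of the 6 wall stress genes none was called over all genes, and 3 with positive and 1 with negative change passed adjusted over the list alone (camera adjusted p = 0.357). VEGFA averaged 158 ± 36.5 in shunt and 97.2 ± 18.2 CPM in control libraries with no overlap (log2 0.70, SE 0.194, edgeR adjusted p = 0.0524), and passed adjusted over the angiogenic and the hypoxia list alone. KDR stood at 0.34 (SE 0.220, adjusted p = 0.316).

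All 13 mitochondrially encoded genes had positive log2 changes, with a median of 1.22, or 0.39 with library totals. CYTB, at 121840 ± 51825 against 48055 ± 5701 CPM, was the 1 called over all genes (log2 1.34, SE 0.355, edgeR adjusted p = 0.0496), and all 13 passed adjusted over the list alone. Together they make up the mitochondrial share of each library, so they are not 13 independent results. The exact permutation test of that share gave p = 0.0857. The set was higher by camera (adjusted p = 1.17e-05, and adjusted p = 0.995 with an estimated correlation). Without shunt 1 and shunt 2 its median was 0.31 and it did not pass (camera adjusted p = 0.104, with 7.97e-08 to 0.104 over the 12 settings tried with the preset correlation). It was the 1 list of 15 that passed in this comparison. The 6 nuclear-encoded genes of oxidative phosphorylation had a median of 0.14 with no call over all genes or over the list alone (camera adjusted p = 0.995), and of -0.50 with library totals. The 7 fatty acid genes had a median of 0.01 with no call, and of -0.51 with library totals. LPL, at -1.25 (SE 0.360, edgeR adjusted p = 0.0579), passed adjusted over the list alone. CPT1B stood at 0.14 (adjusted p = 0.732).

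Neither proliferation gene was called, with CDK1 at -1.08 (SE 0.568, edgeR adjusted p = 0.23) and AURKA at 0.61 (SE 0.426, adjusted p = 0.364). YAP1 was the 1 call among 6 growth regulators, and CDK4, at 0.62 (SE 0.202, adjusted p = 0.0762), passed adjusted over the list alone. The sarcomere genes MYL2, TPM1 and MYOZ2 stood at 0.34, -0.23 and 0.07 with no call. ATF4 was the 1 call among 2 heat shock and unfolded protein genes, also adjusted over the list alone. TIMP1 was the 1 call among 8 fibroblast and matrix genes, and MMP2, a matrix metalloproteinase, at -0.95 (SE 0.301, adjusted p = 0.0723), passed adjusted over the list alone. Of metabolic regulators the thyroid hormone receptor gene THRA, at -0.95 (SE 0.293, adjusted p = 0.0678), and the glucocorticoid receptor gene NR3C1, at -0.42 (SE 0.164, adjusted p = 0.117), passed adjusted over the list alone. PSMB8, an immunoproteasome subunit, at 1.11 (SE 0.321, adjusted p = 0.0582), did so too. The adipocyte genes FABP4, at 3.99 (SE 1.17, adjusted p = 0.0713), and SCD, at -1.45 (SE 0.408, adjusted p = 0.0555), each passed adjusted over the list alone. FGF2, at -0.79 (edgeR adjusted p = 0.0731 over all genes), passed adjusted over the list alone. RELN, the 1 tested lymphatic gene, stood at -1.65 (edgeR adjusted p = 0.101 over all genes) with an unadjusted p under 0.05. Across all genes edgeR gave 3662 with an unadjusted p under 0.05. The endothelial, pericyte, immature contractile, sarcomere, myeloid, lymphocyte, cell cycle inhibitor, cardiac transcription factor, glycolysis and immediate early lists had no member that passed either way.

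In all, 522 of 13065 genes differed between shunt and control libraries by edgeR's quasi-likelihood test, 301 higher and 221 lower in the shunt group, and 12 of each carried a symbol. The 4 and 4 libraries did not overlap for 1585 genes (12.1%, against 2.86% by chance). The count was 8, 6 and 9 without control 1, control 2 and control 4, 36 and 23 without shunt 1 and shunt 2, and 1784 and 2169 without shunt 3 and shunt 4. It was 64 without both shunt 1 and shunt 2, with 34 of the 522 among them, 4 when only the 8 libraries compared entered the fit, and 8 with the mitochondrial share as a covariate. The main fit shares its estimate of spread with the fetal libraries, which vary less than the shunt libraries. The spread in this comparison may thus be understated and the count of 522 too high. Of the 18 genes called and named by the rule, TIMP1 was the 1 that stayed called without each single library of the groups compared (edgeR adjusted p at most 0.00298). TIMP1 and SLC25A5 stayed called without shunt 1 and shunt 2 together (edgeR adjusted p = 0.000439 and 0.0212), and all 18 kept their sign in the settings tried. With library totals 9 of the 18 stayed called, and TIMP1 was the 1 among them that was higher in shunt libraries.

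Between shunt and fetal ventricles, FABP4 and FABP5 were higher and both tested proliferation genes lower in the shunt group. FABP4 (ENSOARG00000009344), a fatty acid binding protein of fat cells and capillary endothelium, averaged 54.0 ± 46.5 CPM in shunt against 0.273 ± 0.433 CPM in fetal libraries (SD, n = 4, edgeR adjusted p = 0.00816). The ratio of its summed counts, 5065 against 27, was 285 after scaling by library size (exact 95% interval for counting error 196 to 433). Of the 27 counts 21 came from fetal 3, and without that library the log2 change of FABP4 moved from 7.86 to 9.82 and stayed called. FABP5 was higher by 3.69 on the log2 scale (SE 0.373, edgeR adjusted p = 0.000179), from 44.1 ± 16.5 to 570 ± 281 CPM. CDK1 had a log2 change of -3.50 (SE 0.594, adjusted p = 0.00299), IGFBP5 of -2.19 (SE 0.376, adjusted p = 0.0029) and EDNRA, an endothelin receptor gene, of -1.70 (SE 0.437, adjusted p = 0.0203).

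All 13 mitochondrially encoded genes were higher in shunt than in fetal libraries, over all genes and adjusted over the list alone, with a median log2 change of 1.97, or 0.81 with library totals, and ND3 at 2.99 (SE 0.530, edgeR adjusted p = 0.0032). With library totals ND6, at 0.51 (edgeR adjusted p = 0.079), was the 1 of the 13 not called. Here too the 13 genes make up the mitochondrial share and are not independent results. The set passed by camera (adjusted p = 1.14e-10, and adjusted p = 0.509 with an estimated correlation), and without shunt 1 and shunt 2 its median was 1.21. Of 6 nuclear-encoded genes of oxidative phosphorylation, NDUFA12, NDUFB6 and ATP5PD were higher, by 0.97, 0.96 and 1.01 (edgeR adjusted p = 0.0121, 0.0232 and 0.019), and 5 were adjusted over the list alone, but with library totals these 3 turned to -0.06, -0.09 and -0.10. The set passed over the other genes (camera adjusted p = 0.00423, and adjusted p = 0.509 with an estimated correlation). Of 7 fatty acid genes UCP2 and SLC25A20 were higher, by 2.34 and 1.11 (adjusted p = 0.00802 and 0.00414), and 3 were adjusted over the list alone (camera adjusted p = 0.028, and adjusted p = 0.509 with an estimated correlation). With library totals SLC25A20 stood at 0.05 (edgeR adjusted p = 0.863), 2 of the 7 were positive and the median turned from 0.63 to -0.40. That set did not pass without fetal 2, shunt 3 or shunt 4 (camera adjusted p = 0.0522, 0.0933 and 0.0769). Of 7 antigen presentation genes 4 were higher over all genes and 4 adjusted over the list alone, and 3 of the 4 called over all genes kept their sign with library totals, where the median turned from 0.63 to -0.44. PSMB8, B2M and IRF1 were higher by 1.98, 1.86 and 1.46 (edgeR adjusted p = 0.00278, 0.000776 and 0.0139), and IRF1 lost its call with library totals (0.52, edgeR adjusted p = 0.3). That set passed by camera (adjusted p = 0.0382, and adjusted p = 0.509 with an estimated correlation), but in only 5 of the 12 settings tried with the preset correlation (camera adjusted p from 0.0175 to 0.106). It did not pass without fetal 3, fetal 4, shunt 1 or shunt 3 (camera adjusted p = 0.0883, 0.0506, 0.0646 and 0.104), nor without shunt 1 and shunt 2 together (camera adjusted p = 0.106).

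Both proliferation genes were lower, with AURKA at -1.32 (edgeR adjusted p = 0.0462). CCND2 and YAP1 were at -1.24 and -1.13 (adjusted p = 0.0256 and 0.00274), PEG10 at -3.89 (adjusted p = 0.000877), NR3C1 at -0.75 (adjusted p = 0.00873) and RELN at -1.91 (adjusted p = 0.0451). In the fibroblast and matrix list TIMP1 and TIMP3 were higher by 1.75 and 1.46 (adjusted p = 0.000527 and 0.0076), and MMP2 and TGFB1 were lower, at -1.36 and -0.66 (adjusted p = 0.00993 and 0.037), and 2 higher and 5 lower passed adjusted over the list alone. CRYAB, a small heat shock protein, was higher by 1.27 (adjusted p = 0.00278) and GNLY by 3.16 (adjusted p = 0.0286). ATF4 was higher by 1.01 (adjusted p = 0.00771), but turned to -0.11 with library totals. TIMP1, TIMP3, CRYAB and GNLY kept their sign there, at 0.76, 0.42, 0.27 and 2.32, but were not called (edgeR adjusted p = 0.0589, 0.294, 0.358 and 0.052). NPPB and NPPA, at 1.65 (SE 1.53) and 2.61 (SE 1.64), were not called (adjusted p = 0.483 and 0.295). VEGFA stood at 0.35 (SE 0.194, adjusted p = 0.222), KDR at -0.41 (SE 0.219, adjusted p = 0.207) and CPT1B at 0.63 (SE 0.229, adjusted p = 0.0719). In all, 2048 of 13065 genes differed by edgeR's quasi-likelihood test, 1197 higher and 851 lower in shunt libraries, with 65 and 29 carrying a symbol, and 2484 genes (19.01%, against 2.86% by chance) did not overlap. The count was 963, 1141 and 957 without fetal 1, fetal 2 and fetal 4, 1226 without shunt 2, 1314 without shunt 1 and shunt 2 together, and 52 with the mitochondrial share, which did not overlap between these groups, as a covariate. EDNRA lost its call without fetal 1, fetal 4 or shunt 2 (edgeR adjusted p up to 0.0651).

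The 3 groups also allow the question of whether the shunt ventricle lay nearer to the fetal one for the genes that differ between fetal and control lambs. ALDH1A1, GSN and FURIN rose from fetal to control by 3.77, 1.44 and 1.17 on the log2 scale and were lower in shunt than in control libraries, at -2.41, -1.29 and -0.93. FABP5 rose by 2.23 and stood a further 1.46 higher in the shunt group, and these 4 are the genes with a symbol called in both comparisons. Of the 675 genes called between control and fetal libraries, 63.4% had a shunt mean on the fetal side of the control mean, 67.0% of those lower and 59.6% of those higher in fetal libraries. Both comparisons use the same control libraries, so an unchanged shunt group gives a high value too. In 20 simulated sets it gave 65.1% on average, from 63.2% to 68.1%, and the observed share did not exceed this. These sets called 1427 genes on average between control and fetal libraries, against 675 observed, so they are not matched to the data in the number of calls. With the controls split 2 and 2, one pair for each comparison, the 6 splits gave 55.3% to 75%, with Pearson r across genes of 0.0586 to 0.161 and a covariance of 0.0328 to 0.0834. Separate pairs share no chance values of the controls, so an unchanged shunt group is expected to give a correlation of about 0 and equal shares on both sides. The 6 splits reuse the same libraries, and their excess was not tested. Across all tested genes, which are not independent replicates, the log2 changes of fetal and of shunt against control correlated at Pearson r 0.238, against 0.245 in the simulations. Their covariance was 0.115 against 0.0755 simulated, a difference of 0.0398, and lay above the simulated range of 0.0683 to 0.0846. The simulations drew each gene independently, so their ranges leave out correlation between genes and are too narrow. A value outside such a range does not by itself show a change shared by shunt and fetal libraries. Among called genes, the median ratio of the shunt to the fetal change, both against control, was 0.165. The simulations gave 0.102, from 0.0895 to 0.125. Called in both were 22 genes higher and 28 lower than control in both groups, and 3 and 4 in opposite directions. If the calls of the 2 comparisons were independent, 7.53 and 5.89 would be expected in the same and 5.53 and 8.02 in opposite directions. The simulated sets gave 0.05 on average (0 to 1) for each of the first 2 and 0 for the others. An unchanged shunt group has close to no calls against control by construction, so these low values are built in and give no baseline. The numbers expected under independence leave out that the shared controls push both comparisons the same way. The excess over them was given no p-value.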

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

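The explanations and tests for the shunt libraries were chosen after shunt 1 and shunt 2 were seen to stand apart and after the counts without single libraries were seen, and the bounds of each test were set before its result, except that the test of lost depth was written after 1 draw of it was seen. The 522 genes called between shunt and control libraries come with mitochondrial shares in shunt 1 and shunt 2 far above the rest. The tables argue against a difference in shunt 1 and shunt 2 alone. Log2 differences of shunt 1 and 2 and of shunt 3 and 4, against separate controls, correlated across genes in all 6 control splits. The r was 0.243 to 0.372, always above a bound of 0.1. The median of 0.329 passed its own bound of 0.3 by less than this spread. Without shunt 1 and shunt 2, 64 genes were called, 34 of them among the 522. This fall does not single out those 2 libraries, since 8, 6 and 9 were called without control 1, control 2 and control 4. The median log2 difference of the called non-mitochondrial genes, in the direction of the call, was 1.42 in shunt 1 and 2 and 0.8 in shunt 3 and 4. Mitochondrial transcripts in the scaling were checked by removing mitochondrial genes, and 93.7% of the other called genes stayed called with the same sign, above a bound of 80%. TMM had already taken out a median shift of -0.61 seen with library totals, and the removal shifted the median by a further -0.019. The test could thus change little, and it speaks to the scaling alone. With the mitochondrial share as a covariate 8 genes were called, 7 of them among the 522. With equal counts on other genes in every library 373 to 606 genes were called over 20 draws (median 513 against 522). All of the called genes that were tested, at least 513 in each draw, kept their sign, and 319 to 420 of 521 stayed called. The kept signs are largely built in, since the thinned counts are part of the counts that made the calls. Most calls as a set thus remained with equal counts on other genes. The lowest draw missed the bound of 80% of 522, so by its bounds the test could not decide. Single calls were not settled. A sample quality axis that follows the mitochondrial share cannot be told apart from an effect of the shunt, which the design names and which was not tested apart from tissue quality, since shunt 3 had a raised share too and slopes on the share within fetal and control libraries correlated across genes with those within shunt libraries at r = 0.169, between the median (-0.005) and the 95th percentile (0.207) of reordered shares.

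Other splits of the same 8 libraries into 4 and 4 were run for each count. For control against fetal, 1 of 35 splits, the real one, called as many as 675 genes, and the highest of the others called 0. For shunt against control, 1 of 35 called as many as 522, and the highest other, with control 3 beside shunt 1, shunt 2 and shunt 4, called 62. For shunt against fetal, 1 of 35 called as many as 2048, and the highest other called 1. In each comparison the real split called the most genes, a share of 2.9%, under 0.05 and the smallest that 35 splits can give. This share treats the libraries as independent, which the labels do not state, and it holds for the main fit. Shunt against control called 4 genes in the fit of the 8 libraries compared. Without control 1, control 2 and control 4 it called 8, 6 and 9, and without control 3 it called 543. Chance was not tested by splits in those fits.

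A library far from the other 3 of its group, by Dixon's ratio at the 95% level, was found for 30 of 327 groups of values (9.2%), where chance gives about 1 in 20. Gene values were compared as log2 CPM. The total of shunt 3 was 42774036 counts against 24944197 to 26615226. In shunt 2, PEG10 and LCK were at 0 CPM, where a count of 0 allows up to 0.264 CPM, against 0.262 to 0.304 and 0.577 to 0.712 CPM in the other shunt libraries. In the same library BGN was at 10.2 against 50.9 to 56.6 CPM, SLC25A20 at 71.8 against 45.6 to 46.7 CPM, CPT1A at 119.5 against 45.1 to 50.3 CPM and MEF2C at 39.6 against 26.9 to 27.7 CPM. In shunt 1, MYL2 was at 10030 against 15060 to 16350 CPM and HADHA at 227 against 459 to 500 CPM. Shunt 3 had KDR at 36.4 against 71.9 to 82.1 CPM and TIMP3 at 199 against 378 to 414.5 CPM. Shunt 4 had CD14 at 4.01 against 1.15 to 1.30 CPM and CD4 at 0.225 against 0.342 to 0.365 CPM.

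Control 3 had CRYAB at 1452 against 1083 to 1137 CPM, ND3 at 11610 against 8379 to 8816 CPM and LCAT at 23.4 against 12.9 to 13.8 CPM. It also had BGN at 69.95 against 56.3 to 57.9 CPM and GHR at 9.82 against 15.2 to 15.7 CPM. Control 1 had MYC at 50.3 against 18.4 to 19.97 CPM and ATP5PO at 758 against 910 to 929.5 CPM. Fetal 3 had NDUFB6 at 349 against 172 to 192 CPM, ATP5MC1 at 302 against 232 to 243 CPM and PEG10 at 1.80 against 3.99 to 4.07 CPM. It also had GHR at 6.94 against 10.5 to 11.2 CPM and FABP4 at 0.923 against 0.0471 to 0.0649 CPM. Fetal 1 had BTG2 at 4.85 against 1.54 to 1.67 CPM and SLC25A5 at 10.5 against 7.24 to 7.30 CPM. Fetal 2 had LPL at 59.9 against 90.1 to 91.6 CPM and PSMB8 at 22.7 against 16.4 to 16.9 CPM, and fetal 4 had FHL1 at 27.7 against 24.1 to 24.4 CPM.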

How the results depend on the processing

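Leaving out shunt 1 and shunt 2 together, the mitochondrial share as a covariate and thinning were chosen after seeing the data, and the other settings were planned. Counts are given for control against fetal, shunt against control and shunt against fetal, in that order, where the main analysis called 675, 522 and 2048 genes. DESeq2-style size factors, removal of mitochondrial genes, no filter, the stricter filter and thinning to 7140136 other counts moved none of the 3 counts by over 1.5 times. Thinning was drawn 20 times for shunt against control and gave 373 to 606 genes. DESeq2's Wald test called 1248 and 1981 in the first 2 comparisons. Limma-voom with quality weights called 2414, 67 and 1299, with weights of 0.3 and 0.315 for shunt 1 and shunt 2. The test against a fold of 1.5 called 170, 5 and 457. Fits of the 8 libraries compared called 1913, 4 and 1073. Without shunt 1 and shunt 2 the counts were 1672, 64 and 1314, and with the covariate 1180, 8 and 52. Fits of the 8 libraries take the spread from fewer libraries, which alone cannot account for both the rise to 1913 and the fall to 4. Shunt libraries correlated less with each other (Pearson r 0.896 to 0.943) than control (0.958 to 0.970) or fetal libraries (0.960 to 0.968). The main fit shares its estimate of spread over these groups, so it may understate the spread in shunt against control. Of the 18 genes called and named by the rule in shunt against control, 1 stayed called in the fit of the 8 libraries compared. The cause was not tested for any setting. Library totals shifted the median log2 change of all genes by -0.41, -0.61 and -1.02, so that 12.3%, 2.2% and 1.7% of calls were higher, against 51.6%, 57.7% and 58.4% with TMM, and called 7933 genes in the last comparison. No called gene chosen by the naming rule changed sign under library totals, while 5 list members called in shunt against fetal did, among them NDUFA12, NDUFB6, ATP5PD and ATF4, which were named after their values were seen. Of the called genes chosen by the naming rule 16 of 22, 9 of 18 and 6 of 6 stayed called there, and of the called list members 5 of 10, 3 of 5 and 25 of 37. VEGFA in shunt against fetal, at 0.35 and not called with TMM, was at -0.68 there, where the median of all genes shifted by -1.02 (edgeR adjusted p = 0.0462, with 0.0462 to 1 over its settings).

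Leaving out single libraries of the 2 groups compared gave 259 to 530, 6 to 2169 and 957 to 2855 genes. The lowest of these counts came without fetal 1, control 2 and fetal 4, and the highest without control 3, shunt 4 and shunt 4. Leaving out a shunt library, which enters the estimate of spread, gave 765 to 886 genes for control against fetal. Of 15 lists, 3, 1 and 4 passed, with 3 to 4, 1 to 2 and 2 to 4 over the single libraries left out, and 0, 0 and 0 with an estimated correlation. Some lists passed only in other settings, 13 each. The wall stress list passed in shunt against control without shunt 1 (median log2 1.15, camera adjusted p = 0.0494) and without shunt 1 and shunt 2 (1.41, camera adjusted p = 0.0107), with 0.0107 to 0.995 over its settings, and antigen presentation without control 3 (0.0427, with 0.0427 to 0.995). In control against fetal the fibroblast list passed in 5 settings (0.0243 to 0.45 over all) and the myeloid list without fetal 3 (0.0376, with 0.0376 to 0.45). In shunt against fetal the myeloid list passed with no filter (0.0411, with 0.0411 to 0.649). The share of genes with the shunt mean on the fetal side was 63.4%, with 60.5% without fetal 3 and 71.5% without control 3 as the lowest and highest, and 66.7% as the median of the control splits.

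With the replicate number as a block, shunt against control had 61 genes, and the other counts, 513 and 1444, moved by less than 1.5 times. The numbers are a shared label, and the labels state no pairing by them. Deviations of same-numbered libraries correlated at -0.19 to 0.154, above 0.1 in 3 of 12 pairs, against 6 of 36 pairs with different numbers. Of 12 libraries 0 correlated best with their own number in both other groups. These values gave no sign of a pairing but cannot exclude a partial one. Over the named genes and settings, 3185 values kept sign and side of the threshold, 285 lost and 149 gained a call with the same sign, 165 changed sign with no call in either setting, and 1 changed sign with a call. For lists these were 518, 19, 10, 38 and 0. Depth limits shunt 1 and shunt 2 most, with 7152139 and 7140136 other counts.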

Other observations

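The genes in this part were chosen after their values were seen. HSD11B1, the enzyme that regenerates active glucocorticoid, averaged 0.583 ± 0.206 CPM in shunt, 2.31 ± 0.529 in control and 0.963 ± 0.369 in fetal libraries (SD, n = 4), with a log2 change of -1.97 between shunt and control libraries (SE 0.398, edgeR adjusted p = 0.0344). HLF, a transcription factor under circadian control, was at 0.406 ± 0.253 CPM in shunt against 2.41 ± 0.898 CPM in control libraries (log2 -2.46, SE 0.493, edgeR adjusted p = 0.0344). It was the 1 called of 11 clock-related genes in that comparison, of which 5 had an unadjusted p under 0.05. Its relative TEF stood at -1.15 (SE 0.351, adjusted p = 0.0671), CRY1 at -0.55 (SE 0.197, adjusted p = 0.0976) and ARNTL at 0.22 (SE 0.469, adjusted p = 0.791). TPSB2, a tryptase of mast cells, was detected in 1 of 4 shunt libraries, at 0.14 CPM, against 0.675 ± 0.567 CPM in control and 1.42 ± 0.532 CPM in fetal libraries (shunt against control edgeR adjusted p = 0.0386).

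TLR5, a receptor of bacterial flagellin, was higher in shunt than in fetal libraries, at 3.47 ± 3.50 against 0.384 ± 0.227 CPM (log2 3.13, SE 0.673, edgeR adjusted p = 0.00827). TLR2, TLR1, TLR6, TLR3 and TLR4 stood at 0.94, 0.72, 0.64, 0.56 and 0.41 with no call. Of 8 families of symbols with at least 4 tested members, 2 passed as a set. The 6 Toll-like receptors passed in shunt against fetal (camera adjusted p = 0.0371, and adjusted p = 0.206 with an estimated correlation) and not in shunt against control (camera adjusted p = 0.273). The 10 genes whose symbols start with ATP, mostly subunits of ATP synthase and ion pumps, passed in control against fetal (camera adjusted p = 0.00818, and adjusted p = 0.279 with an estimated correlation) and in shunt against fetal (camera adjusted p = 0.0363, and adjusted p = 0.242 with an estimated correlation). They include ATP6, ATP8, ATP5MC1, ATP5PD and ATP5PO from the mitochondrial and oxidative phosphorylation lists, so they repeat those results in part. Neither family was tested with library totals. The median of all genes shifted by -1.02 there in shunt against fetal, where the TMM medians were 0.68 for Toll-like receptors and 0.46 for ATP genes. SLC11A1, a metal transporter of phagocytes, was at 1.67 ± 1.42 against 0.0852 ± 0.0631 CPM (edgeR adjusted p = 0.00946), and IDO1, which degrades tryptophan, at 1.74 ± 1.74 against 0.161 ± 0.136 CPM (edgeR adjusted p = 0.0215). Myoglobin, MB, rose from 4611 ± 937 CPM in fetal to 9517 ± 539 CPM in control libraries (log2 1.05, SE 0.240, edgeR adjusted p = 0.0218) and averaged 7189 ± 2273 CPM in shunt libraries (shunt against control edgeR adjusted p = 0.276).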
